A study of Danio rerio with 12 samples.

How the data were processed

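The series comprises 12 zebrafish embryo samples. Of these, 4 are nucleosome maps from micrococcal nuclease digestion, 7 are ChIP-seq libraries of histone marks or RNA polymerase II, and 1 is an RNA-seq library of the 256-cell stage. Processed values of the RNA-seq library alone were used. The other 11 samples were not analysed here, so no comparison between developmental stages or between chromatin marks was made.

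Per the labels' protocols, total RNA was extracted with Trizol, polyA RNA was selected in repeated rounds, and strand-specific libraries were made for paired-end reads of 76 bases. The submitters' processing notes list TopHat 1.1.4 and Cufflinks 1.1.0. The genome build, the annotation release and any filter are not given in the sources used here. The deposited values are FPKM, fragments per kilobase of transcript, scaled to the number of mapped fragments, with 1 value per Ensembl transcript identifier, per the file headers. Cufflinks estimates the abundance of each isoform and divides fragments that match several transcripts among them, so a single transcript's FPKM can be low where its gene has many similar isoforms. The values came without fragment counts, transcript lengths, confidence bounds or a status per transcript. The sequencing depth is therefore unknown, and no counting interval or detection floor was computed. A value of 0 can mean no fragment, fragments all assigned to similar transcripts, or a failed estimate, and these cases were not separated.

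All 54780 identifiers were distinct. The file does not pair them with genes, and 0 of them occurred in the available tables of gene names, which list gene identifiers and RefSeq accessions. No gene name was assigned. The gene-level plan fixed before the data were examined, with 18 gene lists (maternal regulators, early zygotic genes, tissue markers, chromatin and transcription machinery among them), 24 paralog pairs and a rule for naming genes, could therefore not be carried out. None of its lists has a result. The planned counts were made per transcript instead of per gene, and only the transcripts with the 2 highest values are named by identifier.

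From the FPKM values, transcripts at or above fixed levels were counted, with FPKM 1 as the main detection level. The share of the summed FPKM in the 20 highest transcripts and the number of transcripts that made up 50% of the sum were calculated. Alternatives were detection levels of FPKM 0.1, 0.5, 5 and 10, rescaling to TPM (each value divided by the sum of all values and multiplied by 1000000), counting transcripts with a shared value once, and leaving out the highest transcript. With 1 library there is no replicate error, no statistical test between conditions and no p-value. Repeated values and the order of rows were compared with 100 simulations or 100 shufflings of the rows with a fixed seed. In the simulations every value was jittered with an SD of 0.01 on the natural log scale and rounded again to 6 digits. The search for repeated values was first run on simulated data of 50000 rows, where it recovered 60 of 60 planted groups. The planted values were exactly equal, adjacent and higher than all others. Their recovery was therefore given by construction and checks the counting code only. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.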

Results

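The study mapped nucleosomes and chromatin marks at zebrafish promoters around genome activation, the period when the embryo begins to transcribe its own genome. Nucleosome maps were made at the 256-cell stage, 2.5 h after fertilisation, and at the dome stage, 4.5 h after fertilisation, with 2 samples per stage. Trimethylation of histone H3 at lysine 4 was profiled in 3 samples, at 2.5, 3.5 and 4.5 h. The remaining ChIP-seq samples were all from the dome stage: 1 for H3K27me3, 1 for H3K36me3 and 2 for RNA polymerase II, each of the latter with a different antibody. PolyA RNA was sequenced at the 256-cell stage in 1 library without a replicate. The measurements below are from that RNA library, and the chromatin samples were not analysed here. At this stage most embryonic RNA is known to have been laid down by the mother during oogenesis.

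The question asked of the RNA library here was which listed transcripts the polyA RNA of the 256-cell embryo contained and at what level. Of 54780 listed transcripts, 18273 (33.4%) were present at or above FPKM 1. A further 24815 transcripts (45.3%) were listed above 0 but below FPKM 1. The remaining 11692 (21.3%) were listed at 0. At the higher levels, 6815 transcripts (12.4%) reached FPKM 5, 2695 (4.92%) reached FPKM 10 and 55 reached FPKM 100. The detected fraction depended on the level used and was 52.8% at FPKM 0.1. These are counts of transcripts, not of genes, because isoforms could not be joined to their genes. The sequencing depth is unknown and only RNA captured by polyA selection was sequenced. Fragments of one transcript may also have been assigned to similar transcripts. A transcript listed at 0 is therefore not shown to be missing from the embryo.

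Over all listed transcripts the median was FPKM 0.144. Among transcripts above 0 the median was FPKM 0.552, with an interquartile range from 0.0410 to 2.97, and the 95th and 99th percentiles were 11.6 and 29.6. Among transcripts at or above FPKM 1 the median was 3.67, with an interquartile range from 2.03 to 6.99. The fullest interval of the distribution on a log scale, from FPKM 1.78 to 3.16, held 4337 transcripts, and the next, up to 5.62, held 4308. Below FPKM 1 the distribution declined slowly, and 14169 transcripts had values above 0 but under 0.1. A value above 0 can be a part of a fragment divided among transcripts. Low values are therefore not shown to be measured low expression.

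**Figure D1:**
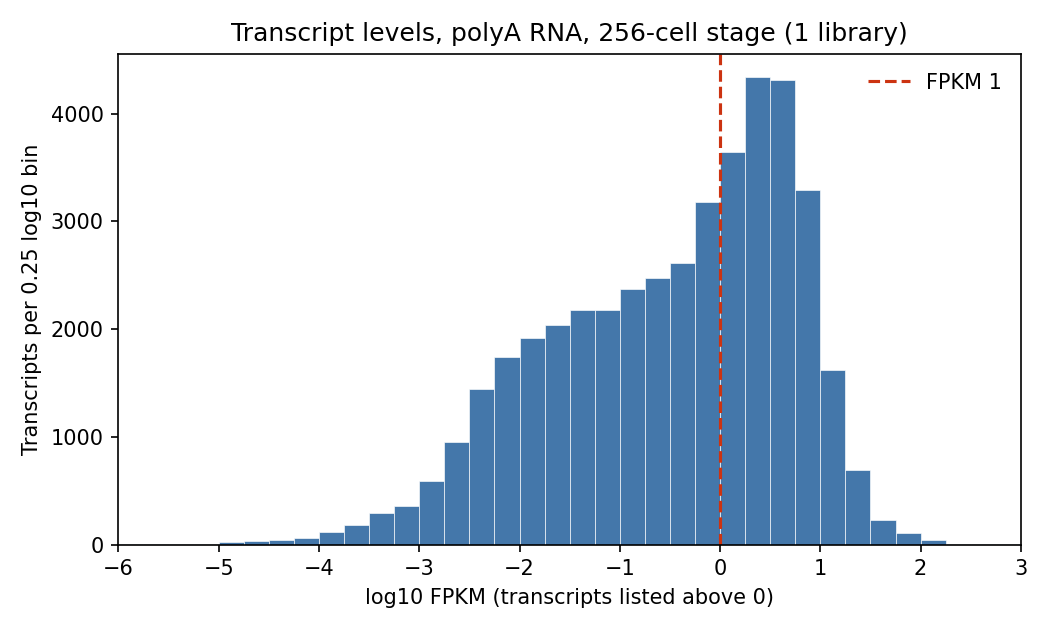
Histogram of log10 FPKM (x axis) for transcripts listed above 0 in the single 256-cell RNA library, as transcripts per bin of 0.25 log10 units (y axis). Of the 43088 such transcripts, the few below log10 FPKM of -6 are not drawn. The dashed line marks FPKM 1, and the fullest bin, from FPKM 1.78 to 3.16, lies to its right with 4337 transcripts.

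The most abundant transcript, ENSDART00000148851, had an FPKM of 770 and contributed 0.609% of the summed FPKM. It was followed by ENSDART00000142111 with an FPKM of 502, or 0.397% of the sum. The gene names of both are not given in the sources used here. The highest value was 210 times the median of the transcripts at or above FPKM 1. Together the 20 highest transcripts held 4.15% of the sum, the 100 highest 10.8%, the 1000 highest 32.4% and the 5000 highest 64.8%. Of the 20 highest, 6 were listed at the identical value of FPKM 163, so their separate levels are uncertain. The transcripts ranked 3, 4 and 5, at FPKM 444, 363 and 235, stood in consecutive rows of the file. Whether they belong to one gene is unknown. The ranking and these shares are therefore per transcript, and could change if isoforms or copies of one gene were joined. To reach 50% of the summed FPKM, 2680 transcripts (4.89% of those listed) were needed, and 13178 (24.1%) were needed to reach 90%. No replicate was available to set these values against biological or technical spread.

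**Figure D2:**
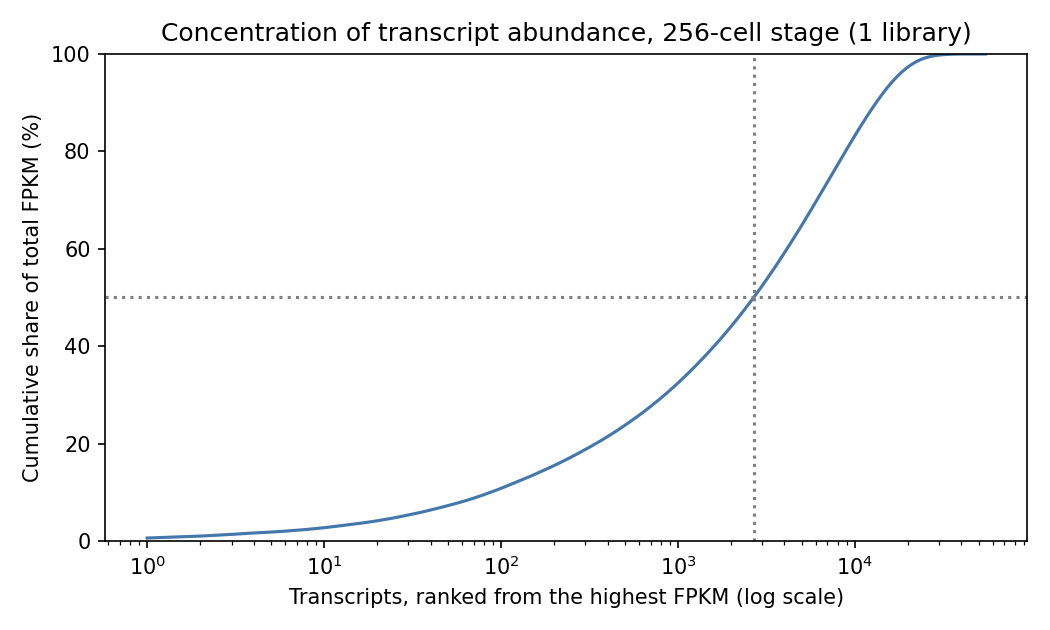
Cumulative share of the summed FPKM (y axis, percent) against the number of transcripts ranked from the highest FPKM (x axis, log scale) in the single 256-cell RNA library. The dotted lines mark 50% of the sum, which was reached with 2680 transcripts.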

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

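The fraction of transcripts detected, 33.4% at FPKM 1, was 52.8% at FPKM 0.1, 40.2% at FPKM 0.5, 12.4% at FPKM 5 and 4.92% at FPKM 10. Rescaled to TPM, 51.0% were at or above 1, because 1 TPM equals an FPKM of 0.127 here. The share of the sum in the 20 highest transcripts, 4.15%, was 3.69% without the highest transcript. Leaving out the highest transcript and counting transcripts with a shared value once were chosen after seeing the data. In those alternatives the number of transcripts needed for 50% of the sum ranged from 2684 to 2717, against 2680. Rescaling to TPM leaves both measures of concentration fixed by construction. The alternatives chosen beforehand that need gene names, isoform groups, lengths, confidence bounds or a status per transcript, and the one that leaves rows at 0 out of the gene-list comparisons, were not run. No paired analysis was possible, because only 1 library was analysed here and no test between groups was made.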

Other observations

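The tests of repeated values within 100 rows, of neighbouring rows, and of rows at 0 alone and rows sharing a value alone, and the description of detection by parts or bins of identifier number, were chosen after the patterns had been seen.

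Detection varied with the number in the transcript identifier. Transcripts were split into 10 equal parts by that number. In the part with the lowest numbers, up to 42831, 52.3% were at or above FPKM 1 and 5.77% were listed at 0. In the part with the highest numbers, from 147835, 27.7% were at or above FPKM 1 and 19.4% were at 0. The fifth part, from 114292 to 123753, stood apart with 57.7% at 0. From the sixth part on, the share at or above FPKM 1 lay between 26.9% and 29.9%, with no steady fall. The share at 0 was 30.7% in the sixth part. In bins of 1000 identifier numbers with at least 100 transcripts, more than 80% of the transcripts were at 0 in 5 bins, which follow one another from 116000 to 120999. These bins were picked for their share at 0. They hold 2226 of the 54780 transcripts and 17.3% of all transcripts at 0. Inside these bins 91.0% were at 0, against 18.4% outside, and 16 transcripts were at or above FPKM 1.

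The summed FPKM was 126530. If every value is the standard FPKM quantity, the listed transcripts account for 12.7% of the mapped fragments per kilobase of their FPKM-weighted mean length. They would account for all mapped fragments only at a weighted mean length of 7.90 kb. The lowest value above 0 was 3.03e-08, and 1138 transcripts were above 0 but under 0.001.

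Some transcripts were listed at exactly the same value above 0. There were 421 values shared by at least 2 transcripts, which lay within the 319 to 429 found in 100 simulations of chance rounding. Values shared by 3 or more transcripts numbered 26, covering 155 transcripts, against at most 7 in the simulations, which argues against rounding as the source of this set as a whole. Of these 26 groups, 8 lay within 100 rows of the file, against 0 in each of 100 shufflings. The largest held 34 transcripts at FPKM 0.000326 within 56 rows. In addition, 14 ordered pairs of neighbouring, different values occurred again elsewhere in the file, against 0 in the shufflings. A candidate explanation for these 8 groups is that Cufflinks divided fragments evenly among identical neighbouring copies of a locus. The other 18 groups spanned more than 100 rows as a whole, but in total 15 of the 26 groups had at least 3 transcripts within 100 rows, against at most 1 in 100 shufflings. Of the 6 transcripts at FPKM 163, 4 lay within 23 rows and the others further off, so copies in part neighbouring stay open for that group. Duplicated records of one locus in the annotation stay open for all of them, since sequences and coordinates were not used here.

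Neighbouring rows of the file had similar values. The rank correlation across transcripts was 0.488 between rows 1 apart, against at most 0.00864 in 100 shufflings, so the rows do not stand at random with respect to level. It fell to 0.332 at 2 rows, 0.180 at 5 rows and 0.111 at 10 rows, and was 0.0675 at 100 rows. Transcripts are not independent replicates, and these values describe this library. Isoforms of one gene listed next to each other may contribute to the near part, which was not tested because no map from transcripts to genes was used. With rows at 0 and rows sharing a value left out, the correlation at 100 rows was 0.0105, inside the shuffled range, whose highest value was 0.0109. The correlation between rows 1 apart was then still 0.373. With rows at 0 alone left out, the correlation at 100 rows was 0.0204, against at most 0.0106 in shufflings, and with rows sharing a value above 0 alone left out it was 0.0661, against at most 0.0157. Neither set alone brought it into the shuffled range. The sizes of these drops cannot be compared, because 11692 rows were at 0 but only 945 shared a value above 0. Leaving out so few rows could hardly change the correlation, so that test says little about rows sharing a value. The drop decides nothing on its own, with rows at 0 left out alone or together with rows sharing a value. Rows are then left out by their own level, which by itself can lower a correlation. Leaving them out also changes which rows are 100 apart. Blocks of identifier numbers alone did not remove the correlation at 100 rows. With ranks taken within each 1000 identifier numbers it was 0.0471, against at most 0.0100 in shufflings. No biological explanation was tested, because the planned comparisons within this library needed gene names, and none could be assigned.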
